A study of Drosophila melanogaster with 24 samples.

How the data were processed

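S2 cells, a Drosophila melanogaster line with hemocyte-like properties, were exposed to Buchnera aphidicola APS, the intracellular symbiont of aphids, and RNA was collected 1, 6 and 24 h later. Per the labels, 4 cultures were sampled at each time, and each was hybridised on 2 arrays against pooled RNA of unexposed S2 cells with the dyes exchanged, which gave 24 arrays. Per the labels' protocols, total RNA was extracted with Trizol and labelled directly by reverse transcription with Cy3 or Cy5. No unexposed culture was hybridised by itself, and the pool was the reference on every array.

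The deposited table holds 1 value per probe and array, and these values were treated here as log2 ratios of exposed cells to the pool. The base of the logarithm, the background correction, the normalization and the filter behind empty cells are not given in the sources used here, so values are called log ratios and no folds are given. Scanner intensities were not used here. The log ratios of the 2 dye-swapped arrays of a culture correlated above 0 in all 12 cultures (r from 0.044 to 0.751, median 0.508), so the deposited ratios had already been turned the same way. That the common direction is exposed over pool is likely, since the design text sets each comparison against the pool, but it is not stated. The lowest correlation between any 2 arrays was -0.12, and the lowest between arrays of the same dye orientation was 0.045.

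The table has 17258 probes. GEO's platform annotation lists 12754 of them, 12658 with 1 gene symbol and 96 with several, and 4504 probes had no symbol. Symbols were updated through the Entrez identifier to the RefSeq annotation of assembly Release 6 plus ISO1 MT for 12012 probes, which was used only for names, and 11980 different symbols resulted. A gene was the mean of its probes (436 genes had more than 1), and a probe with no or several symbols stood by itself. A block of 2716 probes without a symbol was left out as control-like spots. The identifiers of these probes repeat in a regular layout: 20 distances between neighbouring identifiers occur exactly 48 times, and the last 3 digits gave 94.9% of the variance of their mean log ratios, against 7.33% for other probes. Which probes were control-like was decided after seeing the data, and the counts with them kept are given in the closing section.

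The 2 dye-swapped arrays of a culture hold the same extracts and were averaged, so that the replicate was the culture (n = 4 per time). A feature had a value in a culture where both arrays had one, and it was tested with values in at least 3 of 4 cultures at every time. This left 6401 features, of which 5520 were genes with a symbol, 881 were unnamed probes and 5168 had all 12 culture values. Values were used as deposited, without recentring.

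All 12 culture means entered 1 linear model with a mean per time (limma 3.58.1 in R 4.3.3, lmFit and eBayes). Each time mean was tested against 0, which stands for the pool and leaves out the spread of the unexposed cells, and the times were compared by contrasts in which the pool cancels. Moderated tests were two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. For features with all 12 values the prior and residual degrees of freedom summed to 13.5. Gene lists were fixed from textbook knowledge before the data were examined, together with the design, the alternative settings and the rule for named genes. The 26 lists with at least 5 measured members were tested with camera (cameraPR on the moderated statistics, preset correlation 0.01), adjusted over the lists of a comparison. The same lists were tested with an estimated correlation and with fry on the 5168 features with all values. The test with an estimated correlation differs from the first in the members, in the correlation and in its degrees of freedom, which are the residual ones. The preset correlation was therefore also run on the same 5168 features, a setting added after the data were seen. Lists of crystal cell, fat body, muscle, neuron and gut markers had too few measured members and are described by their members. Measured members are those on the array that passed the filter for values, so counts of members leave out the rest. Of the antimicrobial peptide genes 13 were on the array and 8 were measured. For phagocytic receptors and opsonins these were 24 and 8, and for lysozyme, iron and oxidative burst genes 26 and 8.

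Genes were named by rule. For each time, the rule took the 6 largest rises and 6 largest falls among genes past the test with the same sign on all 8 arrays of that time, and from each list the 2 members with the largest change past the test. It took 4 members from the lists of antimicrobial peptides, of peptidoglycan and glucan recognition, and of phagocytic receptors. For each difference between times it took the 5 largest rises and falls among genes past the test that had a value in all 4 cultures of both times and whose culture means did not overlap. Every antimicrobial peptide could be named.

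The number of arrays limits the precision: the median standard error was 0.06 for a time mean and 0.08 for a difference between times. Empty cells left 52.6% to 73.3% of the gene probes with a value on an array, and the medians of these probes ran from -0.11 to 0.13. The calculations were tested on simulated data with the moderated spread of the real cultures, a dye effect and array noise. In the comparison of 1 h with the pool, 52.0% of the changes of 0.25 and 98.0% of those of 0.5 were recovered. Of those of 1 or 2, 100% were recovered, and 5.91% of the calls were false. The simulated pool did not deviate, so this share leaves out false calls from the pool itself. In the further simulation below, with no change but a deviating pool, a mean of 1329 of 6401 features was called at 1 h, likely too many. For 24 h minus 6 h, the shares were 8% at 0.25, 80% at 0.5 and 100% at 1, with 4.0% false calls. None of the 156 list tests was called when only random genes had been changed, and a list moved by 0.3 was found with a median of 0.30. The simulated features varied independently of each other. These list tests therefore do not show whether the preset correlation holds for lists with correlated members.

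A further simulation drew 20 data sets in which no time differed but the pool deviated from the cultures as much as 1 culture does. This deviation took the whole spread of the culture means, array noise included, though array noise is not shared through the pool. The 2 arrays of a culture shared little beyond time and dye (consensus correlation 0.037). The simulated pool therefore likely deviated too much, and the counts called there are likely too high. The alternatives were array centring, array scale, missing values, single probes, the culture number as a replicate block, the dye (a dye term with duplicateCorrelation, or the arrays of 1 orientation), the samples in the fit, robust eBayes, stricter thresholds, and leaving out each culture in turn. Arrays were scaled with limma's normalizeMedianAbsValues, which is what its scale method applies to log ratios. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.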

Results

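The data are 24 arrays of S2 cells exposed to Buchnera aphidicola APS, with 4 cultures at each of 1, 6 and 24 h and 2 dye-swapped arrays per culture, each read against pooled RNA of unexposed S2 cells. An array had values for 10349 to 13367 of the 17258 probes, and 6401 features could be tested. All values are deposited log ratios, treated as log2 and likely exposed over pool, a direction that rests on the design text alone. The positive correlation of the dye-swapped arrays shows only that all ratios share 1 direction, and turned the other way each rise below would be a fall. The first 2 principal components held 47.8% and 24.2% of the variance, and the cultures of each time lay together.

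**Figure D1:**
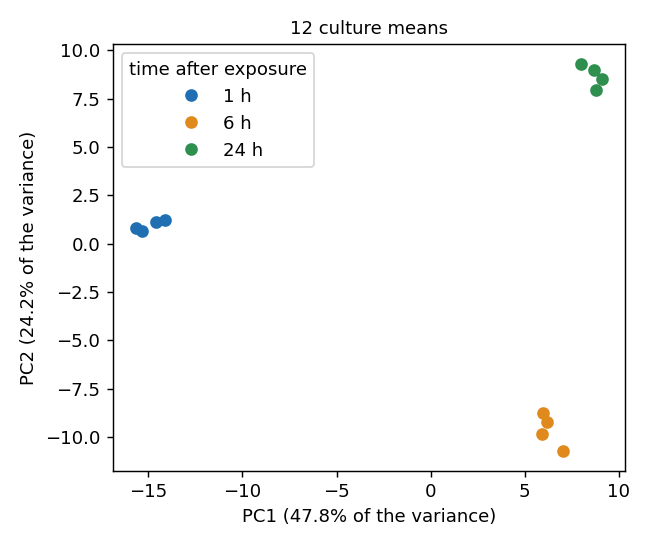
Principal components of the 12 culture means, each point 1 culture and each colour 1 time; the x axis is the first component (47.8% of the variance) and the y axis the second (24.2%), both in units of the component score. The 4 cultures of 1 h lie apart from the others on the first component, and those of 6 h and 24 h lie apart on the second.

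The comparison at 1 h asked which genes had changed early after exposure. Genes of antimicrobial peptides, secreted peptides that kill microbes, were among the largest rises. AttD, an attacin, was at 4.27 ± 0.32 (SD, n = 4), AttB at 3.11 ± 0.08, the diptericin DptB at 2.79 ± 0.09 and edin at 2.75 ± 0.05. All 8 measured members of the list rose (adjusted p = 3.69e-07, adjusted p = 0.090 with an estimated correlation on the 4 members with all 12 values, where the preset correlation gave adjusted p = 0.000146), down to Mtk at 1.96 ± 0.57, Def at 0.93 ± 0.19, Drsl4 at 0.65 ± 0.12 (n = 3) and Drs at 0.63 ± 0.04. Drsl4 missed the threshold without culture 2 (adjusted p = 0.071) or culture 4 (adjusted p = 0.063). Rises outside that list were led by CG4267 at 2.81 ± 0.28 and CG5835 at 2.48 ± 0.09. The largest falls were those of fok at -1.78 ± 0.09, Sirup, an assembly factor of succinate dehydrogenase, at -1.76 ± 0.17, SerT, the serotonin transporter, at -1.31 ± 0.13, and Sesn, a sestrin, at -1.19 ± 0.09.

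Counts of list members are over all features tested, and those adjusted over the list alone were the same unless given. Each adjusted p with an estimated correlation rests on the members with all 12 values and on fewer degrees of freedom, so that a lost call is not put down to the correlation alone. Of 6 recognition genes, 4 rose (adjusted p = 0.0105, adjusted p = 0.098 with an estimated correlation). PGRP-LB and PGRP-SB1, amidases that cleave peptidoglycan, were at 2.04 ± 0.10 and 2.02 ± 0.04, PGRP-LF, a receptor that restrains IMD signalling, at 1.43 ± 0.09, and PGRP-LA at 0.26 ± 0.07 (n = 3). In the list of IMD signalling, the pathway that answers peptidoglycan, 6 of 14 members rose and 1 fell, with 6 and 2 adjusted over the list alone (adjusted p = 0.041, adjusted p = 0.094 with an estimated correlation, adjusted p = 0.050 without culture 2). Rel, its NF-kappaB factor, was at 1.83 ± 0.05 and pirk, its inhibitor, at 1.57 ± 0.03. The Toll list was not shifted (adjusted p = 0.168), though 6 of 14 members rose and 2 fell, among them the inhibitor cact at 0.94 ± 0.03 and the NF-kappaB factor dl at 0.63 ± 0.13.

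Members of the JNK list went both ways (5 of 15 rose and 5 fell, adjusted p = 0.353). Ets21C, an ETS transcription factor, rose to 2.43 ± 0.27 and scaf to 1.95 ± 0.25. Lamellocyte markers rose in 5 of 8 cases (adjusted p = 0.0105, adjusted p = 0.094 with an estimated correlation), led by puc, a phosphatase that restrains JNK, at 1.14 ± 0.17 and the filamin cher at 1.05 ± 0.05, both also in the JNK list. Of 20 genes of actin and phagosome formation, 10 rose, and 1 fell adjusted over the list alone (adjusted p = 0.0105, adjusted p = 0.090 with an estimated correlation), with spri at 0.67 ± 0.05 and Arpc1, a subunit of the Arp2/3 complex, at 0.41 ± 0.04. Apoptosis regulators rose in 6 of 11 cases and fell in 2, with 7 and 2 adjusted over the list alone (adjusted p = 0.041, adjusted p = 0.094 with an estimated correlation). The initiator caspase Dronc was at 0.64 ± 0.10 and its activator Dark at 0.64 ± 0.08. That list's call was lost without culture 1 (adjusted p = 0.056) or culture 3 (adjusted p = 0.062).

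Metal and redox genes included large single rises. Tsf3, a transferrin, was at 1.80 ± 0.02 and Zip99C, a ZIP metal transporter, at 1.67 ± 0.06, in a list where 4 of 8 members rose and 1 fell (adjusted p = 0.082). Gclc, a subunit of the enzyme that starts glutathione synthesis, was at 0.78 ± 0.16 and cnc, the Nrf2 homologue, at 0.75 ± 0.19, in a list where 11 of 24 members rose and 6 fell (adjusted p = 0.075). Of 10 genes of melanization and clotting, 6 rose and 1 fell (adjusted p = 0.0152, adjusted p = 0.166 with an estimated correlation). Pu, the GTP cyclohydrolase of pteridine synthesis, was at 1.30 ± 0.38 and yellow-f at 0.46 ± 0.01.

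Several lists were lower at 1 h. Of 44 genes of DNA replication and cell cycle, 18 fell and 2 rose, with 19 and 2 adjusted over the list alone (adjusted p = 0.00121, adjusted p = 0.090 with an estimated correlation), among them the helicase subunit Mcm5 at -0.45 ± 0.02 and the securin pim at -0.40 ± 0.11. Of 11 plasmatocyte markers, 6 fell and 1 rose, with 7 and 1 adjusted over the list alone (adjusted p = 0.0105, adjusted p = 0.098 with an estimated correlation). The matrix protein Ppn was at -0.98 ± 0.14 and the receptor Pvr at -0.63 ± 0.07. Of 15 genes of glycolysis and lactate, 9 fell and 2 rose, with 10 and 2 adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.126 with an estimated correlation). Pgm1, phosphoglucomutase, was at -0.59 ± 0.05, while sima, the HIF-1 alpha homologue and not a glycolytic enzyme, rose to 0.39 ± 0.17.

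Smaller shifts were found in the cytosolic ribosomal proteins (median -0.07; 4 of 33 fell and 1 rose, with 4 and 0 adjusted over the list alone, adjusted p = 0.040, adjusted p = 0.538 with an estimated correlation and 0.0546 with the preset one on the 29 members with all values, adjusted p = 0.113 without culture 2) and in the proteasome list (median 0.07; 7 of 30 rose and 1 fell, adjusted p = 0.047, adjusted p = 0.438 with an estimated correlation). The proteasome call was lost without culture 1, 3 or 4 (adjusted p = 0.077, 0.074 and 0.092) and with array medians subtracted (adjusted p = 0.050). The culture number as a replicate block also ended the proteasome call. Its fallen member, Prosap at -0.22 ± 0.05, is a synaptic scaffold and no proteasome subunit, and it missed the threshold without culture 2, 3 or 4 (adjusted p = 0.064, 0.052 and 0.089). Heat shock genes were not shifted (11 of 22 rose and 2 fell, with 11 and 5 adjusted over the list alone, adjusted p = 0.091), and the median, mean and test of that list differed in sign. In all, 12 of the 26 lists were shifted and the other 14 had adjusted p from 0.072 to 0.962. Of 6401 features, 2509 changed at 1 h, 1370 higher and 1139 lower, and 105 did so by at least 1, 92 higher and 13 lower. Among simulated data sets with no change but a pool that deviated like 1 culture, a mean of 1329 features was called. That deviation held array noise too, so the count is likely too high as an expected level. How far the pool itself deviated was not measured, so small differences from the pool are not set apart from its own deviation. No culture was handled without bacteria at the same time.

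**Figure D2:**
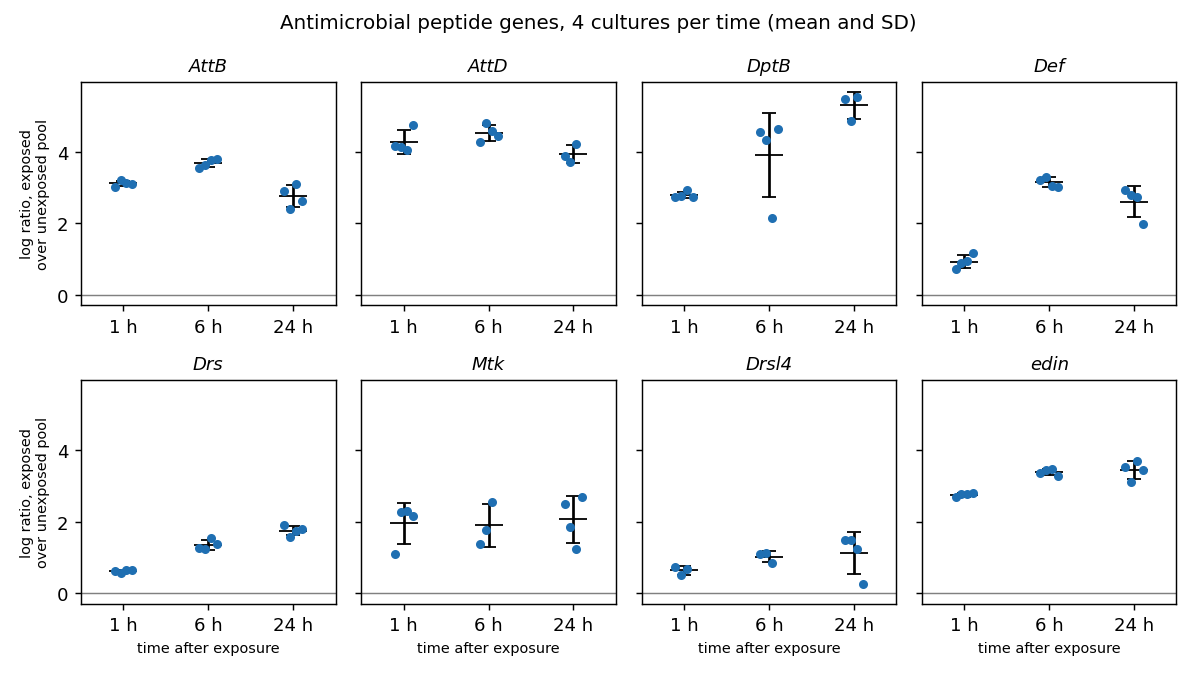
Log ratio of exposed cells over the unexposed pool (y axis, log2 units as deposited) by time after exposure in h (x axis) for the 8 measured antimicrobial peptide genes; points are cultures (4 per time, 3 where a value was missing), and bars are the mean and SD. AttD was near its height at 1 h (4.27), while Def rose from 0.93 at 1 h to 3.15 at 6 h.

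At 6 h the antimicrobial peptide genes were again highest. AttD was at 4.52 ± 0.22 (SD, n = 4), DptB at 3.91 ± 1.17, AttB at 3.68 ± 0.12, edin at 3.39 ± 0.09 and the defensin gene Def at 3.15 ± 0.13. All 8 measured members rose (adjusted p = 4.74e-10, adjusted p = 0.047 with an estimated correlation). Mtk was at 1.90 ± 0.61 (n = 3), Drs at 1.36 ± 0.14 and Drsl4 at 1.02 ± 0.15 (n = 3). In culture 3 DptB was at 2.15, and in the other cultures at 4.31 to 4.62. Outside this list, PGRP-LB was at 2.80 ± 0.08 and ome, a dipeptidyl peptidase, at 2.80 ± 0.20. Among genes with the same sign on all 8 arrays, the largest falls were those of CG9119 at -1.68 ± 0.14, Orct, an organic cation transporter, at -1.38 ± 0.17, the homeobox gene btn at -1.27 ± 0.05, CG8034 at -1.22 ± 0.11, Kah at -1.11 ± 0.12 and NimC4, a receptor for apoptotic cells, at -1.10 ± 0.20.

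Of 57 mitochondrial ribosomal proteins, 36 rose and none fell, with 43 and 1 adjusted over the list alone (median 0.16, adjusted p = 5.75e-09, adjusted p = 0.124 with an estimated correlation). Changes of its members were small, with mRpL20 at 0.33 ± 0.10 and mRpS35 at 0.33 ± 0.05. Of 15 genes of glycolysis and lactate, 10 fell and none rose (median -0.29, adjusted p = 0.000292, adjusted p = 0.047 with an estimated correlation). Pgm1 was at -0.51 ± 0.12 and Pgi, the glucose phosphate isomerase, at -0.40 ± 0.09. Genes of cholesterol and fatty acid synthesis fell in 10 of 16 cases and rose in 3 (adjusted p = 0.00377, adjusted p = 0.105 with an estimated correlation). The acetyl-CoA synthase AcCoAS was at -0.68 ± 0.18 and the fatty acid synthase FASN1 at -0.68 ± 0.19.

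Phagocytic receptors and opsonins fell in 5 of 8 cases (adjusted p = 0.00585, adjusted p = 0.145 with an estimated correlation): NimC4, Dscam1 at -0.58 ± 0.13, the CD36 homologue pes at -0.48 ± 0.07 (n = 3) and drpr, an engulfment receptor, at -0.46 ± 0.10 were among them. Lysosome and autophagy genes fell in 12 of 26 cases and rose in 1 (adjusted p = 0.00774, adjusted p = 0.127 with an estimated correlation and already 0.0647 with the preset one on the 19 members with all values), led by the hexosaminidase Hexo2 at -0.69 ± 0.08 (n = 3) and the lysosomal transporter spin at -0.67 ± 0.09 (n = 3). Of 11 plasmatocyte markers, 6 fell and 1 rose, with 8 and 1 adjusted over the list alone (adjusted p = 0.00377, adjusted p = 0.105 with an estimated correlation). Pvr was at -0.71 ± 0.11 and Glt at -0.69 ± 0.13. Apoptosis regulators now fell in 5 of 11 cases (adjusted p = 0.0130, adjusted p = 0.124 with an estimated correlation): the TNF homologue egr was at -0.88 ± 0.02 and Dark at -0.42 ± 0.12.

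Recognition genes rose at 6 h in 3 of 6 cases and fell in 2 (adjusted p = 0.045, adjusted p = 0.105 with an estimated correlation, adjusted p = 0.055 without culture 2). PGRP-SB1 was at 1.85 ± 0.20, PGRP-LF at 1.31 ± 0.08 and GNBP2 at -0.27 ± 0.12. The call of the recognition list was lost with the arrays scaled to one spread (adjusted p = 0.097) and with the culture number as a replicate block. The JNK list fell in 8 of 15 cases and rose in 2 (adjusted p = 0.045, adjusted p = 0.145 with an estimated correlation and already 0.0841 with the preset one on the 12 members with all values), scaf being at 1.43 ± 0.27. Its call was lost without culture 2, 3 or 4 (adjusted p = 0.055, 0.062 and 0.060). IMD signalling was not shifted (4 of 14 rose and 2 fell, adjusted p = 0.778), with pirk at 0.52 ± 0.08 and imd at 0.42 ± 0.02, nor was Toll signalling (3 of 14 rose and 4 fell, adjusted p = 0.967), where spz, which encodes the ligand of Toll, was at -0.75 ± 0.17 and cact at 0.71 ± 0.06. Median, mean and test differed in sign in both lists. Melanization and clotting genes rose in 6 of 10 cases and fell in 1 (adjusted p = 0.0101, adjusted p = 0.127 with an estimated correlation). Pu was at 1.25 ± 0.25 and Idgf1 at 0.59 ± 0.16.

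Heat shock genes and chaperones rose in 7 of 22 cases and fell in 1 (adjusted p = 0.030, adjusted p = 0.443 with an estimated correlation). Hsp27 was at 0.87 ± 0.18 and the mitochondrial chaperonin Hsp60A at 0.37 ± 0.04. The call was lost without culture 1 (adjusted p = 0.078) or culture 2 (adjusted p = 0.077). Amino acid genes went both ways (6 of 17 rose and 5 fell, adjusted p = 0.787). Gs2, a glutamine synthetase, was at -1.02 ± 0.25 and the transporter path at 0.73 ± 0.01, and here too median, mean and test differed in sign. In all, 12 lists were shifted and the other 14 had adjusted p from 0.053 to 0.967. At 6 h, 2516 features changed, 1265 higher and 1251 lower, and 62 changed by at least 1, 40 higher and 22 lower. The simulated mean with an unchanged group and a deviating pool, likely too high as at 1 h, was 1317.

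**Figure D3:**
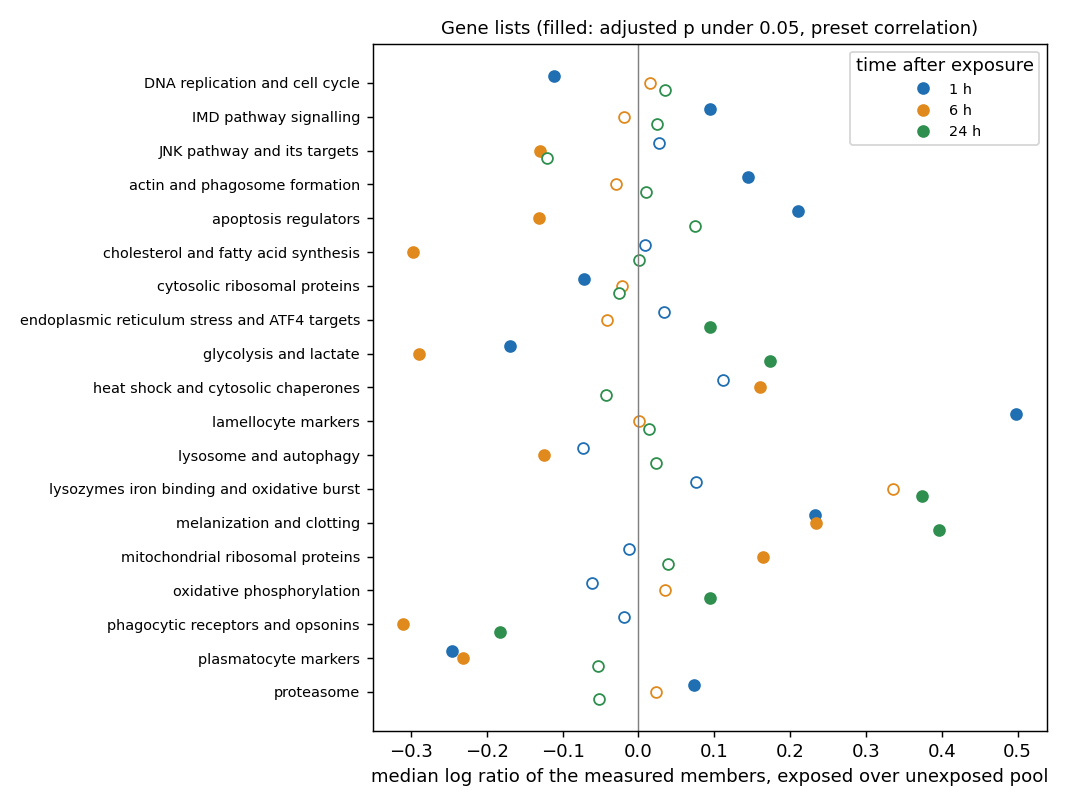
Median log ratio of the measured members (x axis, log2 units as deposited) of 19 gene lists (y axis) at 1, 6 and 24 h; points are list medians, filled where the list was shifted at adjusted p under 0.05 with the preset correlation. The glycolysis list lies at -0.17, -0.29 and 0.17 at the 3 times, and the lamellocyte list at 0.50 at 1 h.

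At 24 h antimicrobial peptide genes were again the highest of the lists. DptB was at 5.29 ± 0.37 (SD, n = 3), AttD at 3.93 ± 0.26 (n = 3), edin at 3.44 ± 0.25 (n = 4), AttB at 2.76 ± 0.30 and Def at 2.61 ± 0.42. All 8 measured antimicrobial peptide genes rose (adjusted p = 2.56e-13, adjusted p = 0.039 with an estimated correlation), including Mtk at 2.07 ± 0.66, Drs at 1.76 ± 0.13 and Drsl4 at 1.12 ± 0.58. MtnA, a metallothionein, was at 2.52 ± 0.10 and CG42807 at 2.23 ± 0.75. The largest falls included CG9119 at -1.22 ± 0.09, CG13731 at -1.20 ± 0.12, nebu at -1.03 ± 0.26, comm2 at -0.90 ± 0.26 and spz at -0.81 ± 0.11.

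Of 6 recognition genes, 4 rose and 2 fell (adjusted p = 0.00336, adjusted p = 0.040 with an estimated correlation). PGRP-LB was at 3.06 ± 0.23 and PGRP-LF at 0.81 ± 0.14. Lysozyme, iron and oxidative burst genes rose in 7 of 8 cases and fell in 1 (adjusted p = 6.54e-05, adjusted p = 0.040 with an estimated correlation). Fer1HCH, the ferritin heavy chain, was at 1.48 ± 0.11 and Zip99C at 1.14 ± 0.08, so the risen members named here handle metals and are not lysozymes. Melanization and clotting genes rose in 7 of 10 cases and fell in 1 (adjusted p = 0.000270, adjusted p = 0.049 with an estimated correlation). Pu was at 1.02 ± 0.36 and Idgf2, a chitinase-like growth factor, at 0.70 ± 0.04. Phagocytic receptors fell in 6 of 8 cases, with 1 rise and 6 falls adjusted over the list alone (adjusted p = 0.039, adjusted p = 0.297 with an estimated correlation and already 0.0710 with the preset one on the 6 members with all values), among them Dscam1 at -0.39 ± 0.11 and pes at -0.25 ± 0.07. That call was lost without culture 1 (adjusted p = 0.059) or culture 3 (adjusted p = 0.078).

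Glycolysis genes rose at 24 h in 8 of 15 cases, 9 adjusted over the list alone (median 0.17, adjusted p = 0.00272, adjusted p = 0.040 with an estimated correlation). Pgm1 was at 0.43 ± 0.03 and Pgi at 0.40 ± 0.04. Genes of oxidative phosphorylation rose in 11 of 25 cases (adjusted p = 0.00272, adjusted p = 0.227 with an estimated correlation). The complex I subunit ND-75 was at 0.43 ± 0.07 and COX5B at 0.31 ± 0.04. In the list of endoplasmic reticulum stress and ATF4 targets, 6 of 26 members rose and 2 fell, with 11 and 2 adjusted over the list alone (adjusted p = 0.00498, adjusted p = 0.047 with an estimated correlation). Herp was at 0.35 ± 0.10, while crc, the ATF4 homologue itself, was at -0.34 ± 0.09.

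Plasmatocyte markers rose at 24 h in 3 of 11 cases and fell in 4, with 3 and 5 adjusted over the list alone (adjusted p = 0.342). Glt was at -0.73 ± 0.12 and the peroxidasin Pxn at -0.62 ± 0.09. The redox list held MtnA but was not shifted (6 of 24 rose and 3 fell, adjusted p = 0.422), and its median differed in sign from its test. JNK members fell in 6 of 15 cases and rose in 1 (adjusted p = 0.051). Ets21C was at -0.72 ± 0.09. DNA replication and cell cycle (adjusted p = 0.398), the mitochondrial ribosomal proteins (adjusted p = 0.116), the cytosolic ribosomal proteins (adjusted p = 0.747) and the proteasome (adjusted p = 0.222) were not shifted. In all, 8 lists were shifted and the other 18 had adjusted p from 0.051 to 0.995. At 24 h, 2049 features changed, 962 higher and 1087 lower, and 51 changed by at least 1, 43 higher and 8 lower. The simulated mean with a deviating pool, likely too high as at 1 h, was 1318. With the control-like probes kept, whose values largely repeat, 3123 features were higher and 1133 lower.

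The difference of 6 h minus 1 h asked what changed after the early response, and the pool cancels in it. Most large differences were falls: 99 features differed by at least 1, 91 lower at 6 h and 8 higher, or 91 higher and 8 lower if the ratios are pool over exposed. Among genes with a value in all 4 cultures of both times, the largest were those of Ets21C with a difference of -2.93 ± 0.13 (SE, n = 4 per time), CG10011 at -1.83 ± 0.08, KrT95D at -1.81 ± 0.06, CG13917 at -1.77 ± 0.13 and CG42327 at -1.75 ± 0.13. Def rose by 2.21 ± 0.17, SerT by 1.72 ± 0.09, ome by 1.55 ± 0.14, the kinase gene Dyrk2 by 1.20 ± 0.08 and CG9815 by 1.13 ± 0.16. Among genes with a symbol, 37 were higher by at least 1 at 1 h and fell by at least 1 by 6 h. Their median log ratio was 1.29 at 1 h, -0.13 at 6 h and -0.03 at 24 h, and 32 of them were within 0.5 of the pool at 6 h. Rel went from 1.83 to 0.19 (adjusted p = 1.30e-09), pirk from 1.57 to 0.52 (adjusted p = 2.62e-06) and puc from 1.14 to -0.43 (adjusted p = 1.91e-06).

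Mitochondrial ribosomal proteins were higher at 6 h than at 1 h in 32 of 57 cases and lower in none, with 33 and 1 adjusted over the list alone (adjusted p = 1.57e-07, adjusted p = 0.122 with an estimated correlation). Antimicrobial peptide genes were higher in 4 of 8 cases, 5 adjusted over the list alone (adjusted p = 0.00173, adjusted p = 0.083 with an estimated correlation), a call lost with the arrays scaled to one spread (adjusted p = 0.068). Genes of DNA replication and cell cycle were higher in 12 of 44 cases and lower in 2 (adjusted p = 0.00177, adjusted p = 0.078 with an estimated correlation). Apoptosis regulators were lower in 9 of 11 cases and higher in 1 (adjusted p = 0.000768, adjusted p = 0.046 with an estimated correlation), phagocytic receptors lower in 6 of 8 (adjusted p = 0.00125, adjusted p = 0.083 with an estimated correlation) and lamellocyte markers lower in 6 of 8 (adjusted p = 0.00173, adjusted p = 0.056 with an estimated correlation). Lower too were the lists of cholesterol and fatty acid synthesis (9 of 16, adjusted p = 0.00173, adjusted p = 0.078 with an estimated correlation), JNK (6 of 15, adjusted p = 0.00173, adjusted p = 0.056 with an estimated correlation) and actin (9 of 20, with 1 higher adjusted over the list alone, adjusted p = 0.00901, adjusted p = 0.067 with an estimated correlation). The other 17 lists had adjusted p from 0.051 to 0.692. Of 6401 features, 2258 differed, 1001 higher and 1257 lower at 6 h, against a mean of 0.05 in the simulation without change. With the control-like probes kept, whose values largely repeat, 2896 were higher and 1263 lower.

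**Figure D4:**
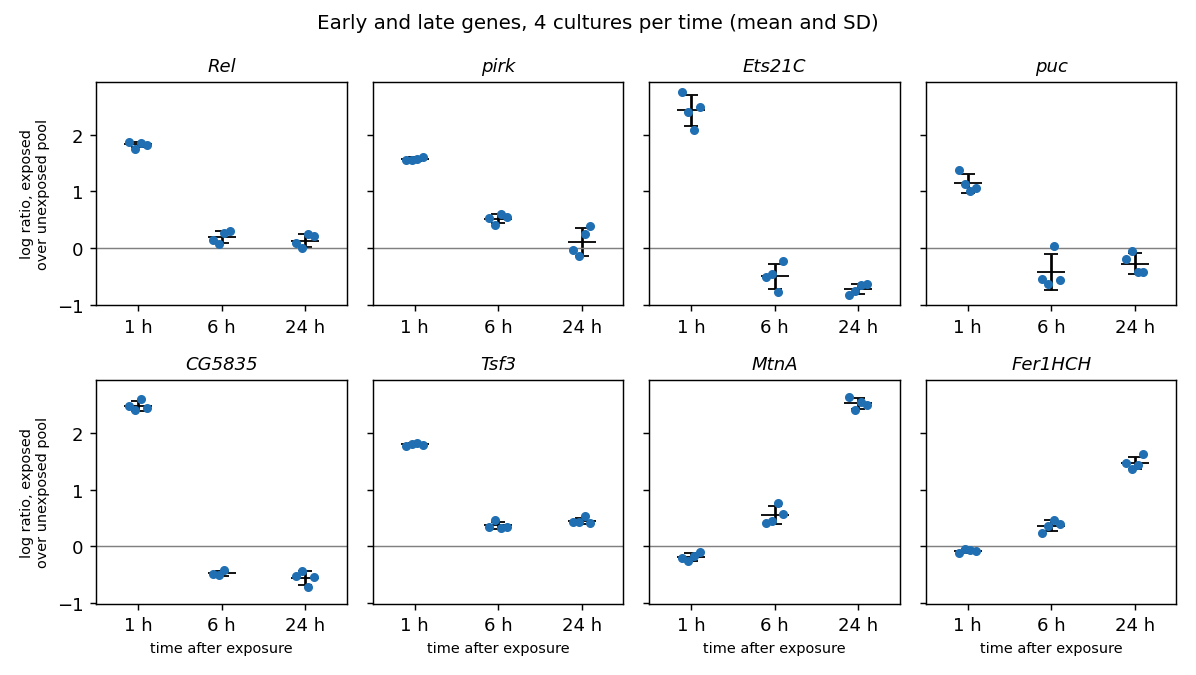
Log ratio of exposed cells over the unexposed pool (y axis, log2 units as deposited) by time after exposure in h (x axis) for 8 genes; points are cultures (4 per time, 3 where a value was missing), and bars are the mean and SD. Rel, pirk, Ets21C, puc, CG5835 and Tsf3 are high at 1 h and lower at 6 h (Rel 1.83 and 0.19), while MtnA and Fer1HCH are high at 24 h (2.52 and 1.48).

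The difference of 24 h minus 6 h asked what changed late. Among genes with a value in all 4 cultures of both times, the largest rises were as follows: MtnA, a metallothionein, rose by 1.97 ± 0.08 (SE, n = 4 per time), the transporter gene MFS3 by 1.26 ± 0.09, CG17032 by 1.22 ± 0.12, CG9485, a glycogen debranching enzyme, by 1.17 ± 0.10 and Fer1HCH by 1.12 ± 0.07. Falls included CG4267 at -1.59 ± 0.12, Ak6 at -1.12 ± 0.08, the G protein gene Galphaf at -1.12 ± 0.11 and CG11837 at -1.04 ± 0.09. Glycolysis genes were higher in 12 of 15 cases, 13 adjusted over the list alone (median difference 0.40, adjusted p = 7.90e-07, adjusted p = 0.012 with an estimated correlation). Mitochondrial ribosomal proteins were lower in 18 of 57 cases and higher in 1, with 19 and 1 adjusted over the list alone (adjusted p = 0.000430, adjusted p = 0.392 with an estimated correlation). Genes of cholesterol and fatty acid synthesis were higher in 8 of 16 cases and lower in 1 (adjusted p = 0.00805, adjusted p = 0.280 with an estimated correlation), and apoptosis regulators higher in 4 of 11, 6 adjusted over the list alone (adjusted p = 0.00756, adjusted p = 0.195 with an estimated correlation).

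Heat shock genes were lower at 24 h than at 6 h in 6 of 22 cases (adjusted p = 0.00809, adjusted p = 0.392 with an estimated correlation, adjusted p = 0.077 without the fourth 24 h culture). Lysosome genes were higher in 9 of 26 cases and lower in 2, with 13 and 4 adjusted over the list alone (adjusted p = 0.031). On the 19 members with all values the list was not shifted (adjusted p = 0.435 with the preset correlation and adjusted p = 0.569 with an estimated correlation). Its call was also lost without culture 2 (adjusted p = 0.054) or culture 4 (adjusted p = 0.050) of 24 h. Antimicrobial peptide genes went both ways: Drs rose by 0.40 ± 0.08 and DptB by 1.38 ± 0.46 (n = 3 at 24 h), while falls were found for AttB (-0.93 ± 0.12), AttD (-0.59 ± 0.17, n = 3 at 24 h) and Def (-0.54 ± 0.17), and the list was not shifted (adjusted p = 0.844). Most of these differences depended on the setting. With the arrays scaled to one spread AttD differed by 0.05 (adjusted p = 0.943), and AttB (adjusted p = 0.088) and Def (adjusted p = 0.629) missed the threshold. DptB missed it without culture 1 (adjusted p = 0.105) or 3 (adjusted p = 0.114) of 24 h, and it differed by 0.80 without culture 3 of 6 h. Def missed it without culture 1 (adjusted p = 0.060) or 2 (adjusted p = 0.074) of 6 h, and differed by -0.33 without culture 4 of 24 h. AttD missed it without culture 2 (adjusted p = 0.066) or 3 (adjusted p = 0.052) of 6 h and without culture 1 (adjusted p = 0.066) or 2 (adjusted p = 0.104) of 24 h. The other 20 lists had adjusted p from 0.061 to 0.993. In all, 1740 features differed, 877 higher and 863 lower at 24 h, of which 15 and 8 differed by at least 1.

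The difference of 24 h minus 1 h compared the ends of the course. MtnA rose by 2.71 ± 0.08 (SE, n = 4 per time), Sirup by 2.61 ± 0.11, CG42807 by 2.00 ± 0.28, SerT by 1.72 ± 0.09 and Def by 1.68 ± 0.17. Among genes with a value in all 4 cultures of both times, the largest falls were Ets21C at -3.15 ± 0.13, CG5835 at -3.03 ± 0.07, CG4267 at -2.49 ± 0.12, scaf at -2.02 ± 0.19 and CG10011 at -1.75 ± 0.08. Genes of DNA replication and cell cycle were higher at 24 h in 18 of 44 cases and lower in 2 (adjusted p = 0.00238, adjusted p = 0.180 with an estimated correlation), those of oxidative phosphorylation higher in 10 of 25 (adjusted p = 0.00236, adjusted p = 0.218 with an estimated correlation) and those of glycolysis higher in 8 of 15, 10 adjusted over the list alone (adjusted p = 0.00235, adjusted p = 0.157 with an estimated correlation). Lamellocyte markers were lower in 5 of 8 cases (adjusted p = 0.0127, adjusted p = 0.157 with an estimated correlation).

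Weaker shifts between 24 h and 1 h were those of the proteasome list (9 of 30 lower, 8 adjusted over the list alone, adjusted p = 0.043, adjusted p = 0.456 with an estimated correlation) and of the antimicrobial peptide genes (4 of 8 higher and 1 lower, adjusted p = 0.0485, adjusted p = 0.254 with an estimated correlation, adjusted p = 0.058 with array medians subtracted). The proteasome call was lost without culture 1, 3 or 4 of 1 h (adjusted p = 0.061, 0.060 and 0.058) and without culture 1, 2 or 3 of 24 h (adjusted p = 0.063, 0.062 and 0.051). The antimicrobial call was lost without culture 1 or 3 of 1 h (adjusted p = 0.061 and 0.060) and without culture 1 or 3 of 24 h (adjusted p = 0.063 and 0.077). The other 20 lists had adjusted p from 0.088 to 0.971. Of 6401 features, 2550 differed, 1115 higher and 1435 lower at 24 h, and 30 and 80 differed by at least 1. With the control-like probes kept, whose values largely repeat, 3040 were higher and 1430 lower.

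The calls against the pool at different times overlapped. At 1 h and 6 h, 415 features were higher and 466 lower at both times, against 271 and 223 for independent lists, and 380 went opposite ways. At 6 h and 24 h, 367 were higher and 465 lower at both (190 and 212 for independent lists) and 332 opposite, and at 1 h and 24 h, 276 were higher and 235 lower at both (206 and 193) and 511 opposite. The pool is shared by all times: unchanged groups against 1 deviating pool gave means of 383, 380 and 382 features higher and 377, 369 and 378 lower at both times, and 0.3, 0.35 and 0.5 opposite. The covariances of the log ratios across features were 0.0390, 0.0435 and 0.0224 (r = 0.42, 0.57 and 0.27), against 0.0168 in each pair of simulated groups, where r was 0.79. Features are not independent replicates, and the pool could not be split. For features higher at 6 h and 24 h the simulated counts were above the observed ones. The same held for those higher or lower at 1 h and 24 h, and the other simulated counts were below. The simulated groups had almost no opposite calls, lower covariances and a higher r, so they do not resemble the data. How much of the excess over independent lists the pool gives was therefore not determined, and it may be part or all. By at least 1, 19 features were higher and 4 lower at all 3 times, among the higher AttB, AttD, DptB, Mtk, edin, PGRP-LB, PGRP-SB1, Pu, Zip99C and ome.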

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

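The tests of carried-over RNA, handling, dye bias, centring and use of the medium were chosen only after the results were seen, while the tests of a common offset and of other splits of the cultures were chosen before.

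The 8 cultures of a contrast can be split into 4 and 4 in 35 ways. For 6 h minus 1 h, the real split gave 2248 features when only these times were fitted and the highest other split gave 3, for 24 h minus 6 h 1498 and 0, and for 24 h minus 1 h 2602 and 2. Each time the real split alone reached the count, which is the smallest share that 35 splits allow (1 of 35). In the other splits the difference between times adds to the spread within groups, so their counts were bound to be low. These counts therefore do not exclude chance. For gene lists the counts cannot decide about chance either. Counting the real one, 8 splits of 6 h and 1 h gave at least its number of shifted lists (9). The highest other split gave 12. Counted the same way, 2 splits of 24 h and 6 h did (6, highest other 7). For 24 h and 1 h, 3 did (6, highest other 7). Each other split that reached the count put 3 cultures of 1 time with 1 of the other. It thus kept part of the difference between times and does not stand for unchanged cultures. Splits with 2 cultures of each time on both sides gave at most 3, 3 and 1 shifted lists in the same order. In those the difference between times again added to the spread within groups.

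Genes high at 1 h and low again by 6 h were the first pattern: CG5835 (difference 6 h minus 1 h -2.95), Ets21C (-2.93), CG10011 (-1.83), KrT95D (-1.81), CG13917 (-1.77) and puc (-1.56) belong to it. Dark (-1.06) went the same way but was at 0.64 at 1 h, below the limit of 1 set for these genes. A first explanation is a brief response to the bacteria, which may be what Rel and pirk show. RNA carried over from aphid cells remains open: the median of the cytosolic ribosomal proteins was -0.072 at 1 h, but their high level in S2 cells would hide a small share, and RNA of the bacteria was not tested. Handling of the cells remains open too, since the heat shock list was not shifted (adjusted p = 0.091) although 11 of its 22 members rose. A culture handled without bacteria would set handling apart, but it would not separate carried-over RNA from a response.

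Between 6 h and 24 h the glycolysis list went from low to high (median difference 0.40 for 24 h minus 6 h, adjusted p = 0.012 with an estimated correlation). From 1 h to 24 h its median difference was 0.27, a shift lost with an estimated correlation (adjusted p = 0.157). Centring of the arrays was not decided: the list stayed shifted with array medians subtracted (adjusted p = 7.64e-07), but the subtraction moved almost nothing in this contrast. Use of the medium with time in culture may explain it as well as the exposure, and the list of endoplasmic reticulum stress and ATF4 targets, which starvation would move, left this open (adjusted p = 0.156). Unexposed cultures of the same age would be needed.

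Control-like probes were the third pattern. The mean of their culture medians was 0.23 at 1 h, 0.66 at 6 h and 0.70 at 24 h. Dye bias was argued against, because the medians were above 0 on 24 of 24 arrays of both orientations, and a common offset was argued against by their median correlation of 0.75 between dye-swapped arrays. What these spots hold is not given in the sources used here, so they may carry real signal that was left out.

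Further list medians differed between 6 h and 1 h: mitochondrial ribosomal proteins (0.21), antimicrobial peptides (0.60), DNA replication and cell cycle (0.10), apoptosis regulators (-0.36), phagocytic receptors (-0.41), cholesterol and fatty acid synthesis (-0.26), JNK (-0.23), lamellocyte markers (-0.33) and actin (-0.18). Of these, apoptosis regulators kept their call with an estimated correlation (adjusted p = 0.046) and the other 8 lost it (adjusted p = 0.056 to 0.122), and the antimicrobial peptides lost it also with the arrays scaled (adjusted p = 0.068). Between 24 h and 6 h these were mitochondrial ribosomal proteins (-0.14), apoptosis regulators (0.18), cholesterol and fatty acid synthesis (0.16), heat shock (-0.15) and lysosome genes (0.20). The first 4 lost their call with an estimated correlation (adjusted p = 0.195 to 0.392), and the lysosome list lost it already with the preset correlation on its 19 members with all values (adjusted p = 0.435). Between 24 h and 1 h they were oxidative phosphorylation (0.15), DNA replication and cell cycle (0.14), lamellocyte markers (-0.50), the proteasome (-0.12) and antimicrobial peptides (0.58), each lost with an estimated correlation (adjusted p = 0.157 to 0.456).

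Some genes lay on opposite sides of the pool at 2 times. From 1 h to 6 h, SerT differed by 1.72 and CG9815 by 1.13. From 6 h to 24 h, Sirup differed by 2.45, MFS3 by 1.26, CG9485 by 1.17, Ak6 by -1.12 and CG11837 by -1.04. From 1 h to 24 h, MtnA differed by 2.71, Sirup by 2.61, SerT by 1.72, CG9815 by 1.55, Ppn by 1.14, MFS3 by 1.08, CG9485 by 1.03, Pgm1 by 1.02, puc by -1.41, CG10011 by -1.75, CG5835 by -3.03 and Ets21C by -3.15. Without the pool's true level the side of a gene near 0 is not certain, but the differences do not involve the pool.

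Dixon's ratio was tested on 198 groups of culture values of genes and 81 of list medians or array summaries. Of these, 21 had a culture apart, and chance alone gives about 1 in 20. Among genes at 1 h these were AttD in culture 4 (4.75), Mtk in culture 1 (1.11), Dronc in culture 3 (0.49), and in culture 2 RpLP2 (-0.43), sima (0.14) and pes (0.11). At 6 h they were DptB (2.15) and puc (0.042) in culture 3 and Irk3 (-0.28) in culture 2. At 24 h they were CG9119 (-1.09), Zip99C (1.02) and barr (0.28) in culture 2, and nebu (-0.65) and elav (-0.040) in culture 4. List medians apart were those of IMD signalling in culture 3 (0.060), apoptosis regulators (0.054) and cholesterol synthesis (-0.00058) in culture 2 and lamellocyte markers in culture 4 (0.67) at 1 h, the proteasome in culture 3 (0.11) and cholesterol synthesis in culture 4 (-0.36) at 6 h, and cytosolic ribosomal proteins in culture 4 (-0.063) at 24 h.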

How the results depend on the processing

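Only after the data were seen, 4 alternatives were added: the preset correlation on features with all values, keeping the control-like probes, using only genes with a symbol, and leaving out the culture of each time whose dye-swapped arrays correlated least (r = 0.348, 0.402 and 0.044).

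Requiring a log ratio of at least 1 left 105 features at 1 h, 62 at 6 h, 51 at 24 h, 99 for 6 h minus 1 h, 23 for 24 h minus 6 h and 110 for 24 h minus 1 h, and overlaps of 32 (1 h and 6 h), 34 (6 h and 24 h) and 26 (1 h and 24 h). An adjusted p under 0.01 left 1179 at 24 h, 1475 for 6 h minus 1 h, 1081 for 24 h minus 6 h and 1680 for 24 h minus 1 h. Arrays with the exposed RNA in Cy3 alone gave 1482 for 6 h minus 1 h and 1078 for 24 h minus 6 h, and those with Cy5 alone 1421, 888 and 1558 for 24 h minus 1 h. With the control-like probes kept, 3688 features changed at 1 h (2597 higher and 1091 lower), 5083 at 6 h (3793 and 1290), 4256 at 24 h (3123 and 1133), 4159 for 6 h minus 1 h (2896 and 1263), 1434 for 24 h minus 6 h (727 and 707) and 4470 for 24 h minus 1 h (3040 and 1430). Most calls were then higher at 24 h, for 6 h minus 1 h and for 24 h minus 1 h, where without these probes most were lower. The 2716 added probes have 205 identifier endings, which gave 94.9% of the variance of their mean log ratios. They largely repeat each other and are not independent features. Of the calls made without them, 2049 of 2049, 2258 of 2258 and 2541 of 2550 kept their direction in these comparisons. The turn therefore comes from the added probes.

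The culture number as a replicate block gave 2375, 2378 and 1899 features at the 3 times and 2121, 1573 and 2404 between them, with 11, 11, 9, 9, 7 and 6 shifted lists in the same order. Under it the proteasome list at 1 h (adjusted p = 0.0506) and the recognition list at 6 h (adjusted p = 0.0551) lost their calls, and the cause was not tested. Equal culture numbers gave no sign of pairing across times: of 12 pairs, 0 correlated above 0.1, and the median r was -0.00144, against -0.0064 for different numbers. The 2 arrays of a culture shared little beyond time and dye (consensus correlation 0.037), so a weak pairing would not show. The labels do not say whether equal numbers pair, and this stays open.

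Leaving out a culture at a time gave 2064 to 2121 features at 1 h, 2143 to 2268 at 6 h, 1518 to 1746 at 24 h, 1950 to 2102 for 6 h minus 1 h, 1446 to 1635 for 24 h minus 6 h and 2196 to 2457 for 24 h minus 1 h. Shifted lists numbered 10 to 11, 9 to 13, 7 to 8, 9 to 11, 4 to 7 and 4 to 6 in the same order.

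With an estimated correlation within lists, 0 lists were shifted at 1 h, 2 at 6 h, 6 at 24 h, 1 for 6 h minus 1 h, 1 for 24 h minus 6 h and 0 for 24 h minus 1 h. These tests used only features with all values and fewer degrees of freedom. With the preset correlation on the same features 11, 10, 7, 10, 5 and 6 lists were shifted, and the lists of cytosolic ribosomal proteins at 1 h, lysosome and JNK at 6 h, phagocytic receptors at 24 h and lysosome for 24 h minus 6 h lost their calls (adjusted p = 0.0546, 0.0647, 0.0841, 0.0710 and 0.435), and the cause was not tested. Over the 6 comparisons in the order above fry called 22, 20, 17, 19, 16 and 18 lists, and its mixed test 25, 26, 25, 26, 25 and 26.

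Signs turned for a few genes. At 24 h, where lok (0.20) and S1P (-0.23) had passed the test, lok was at -0.029 with 1 array per culture enough and at -0.062 with Cy5 alone, and S1P at 0.053 with Cy5 alone. AttD differed by 0.052 for 24 h minus 6 h and by 0.25 for 24 h minus 1 h with the arrays scaled. With Cy5 alone Mtk differed by 0.30 for 6 h minus 1 h, -0.48 for 24 h minus 6 h and -0.17 for 24 h minus 1 h, and Drsl4 by -0.17 for 24 h minus 6 h. Without the cultures of lowest correlation Mtk differed by -0.30 for 24 h minus 6 h and -0.39 for 24 h minus 1 h. Leaving out a culture at a time, Mtk ran from -0.40 to 0.20 for 6 h minus 1 h, from -0.095 to 0.50 for 24 h minus 6 h and from -0.18 to 0.38 for 24 h minus 1 h. Drsl4 ran from -0.026 to 0.39 and edin from -0.029 to 0.17 for 24 h minus 6 h. Among these differences between times, that of AttD between 24 h and 6 h had passed the test and the others had not. Of the settings tried on named genes, 5055 left the sign and the call the same, where a gene not called in either also counted. Sizes were not compared. In 385 a call was lost, in 10 one was gained and in 24 the sign turned. For lists, 585 settings left the call and 82 lost it. Among the 53 shifted pairs of list and comparison on which alternatives were run, no list test changed direction. The signs of the medians were not compared.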

Other observations

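No test in this part was chosen only after its result was seen, as the lists below were fixed earlier.

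Some lists were not shifted at any time. JAK-STAT signalling (adjusted p = 0.308 at 1 h, 0.660 at 6 h and 0.995 at 24 h) held Tep4, a thioester protein, at 0.84 at 1 h and 0.70 at 24 h, and the repressor chinmo at -0.64 at 1 h. Ecdysone response genes (adjusted p = 0.316, 0.061 and 0.297) held the receptor EcR at -0.48 at 6 h. In the list of amino acid transport (adjusted p = 0.429, 0.787 and 0.192) path was at 0.73 at 6 h and Gs2 at -0.63 at 24 h. Cholesterol and fatty acid synthesis was shifted against the pool at 6 h alone (adjusted p = 0.105 with an estimated correlation), with Lip4, a lipase, at 0.54 and Hmgs at 0.32 at 1 h.

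Markers of other cell types had too few measured members for a test. Their called members went both ways. Of the fat body list, Apoltp, a lipid transfer protein, fell to -0.69 at 24 h, and Mtp rose to 0.19 at 1 h, a call lost without culture 1 (adjusted p = 0.078) or culture 4 (adjusted p = 0.062). The muscle marker Msp300 rose to 0.30 at 1 h and 0.35 at 6 h. Of the crystal cell list, Men fell to -0.46 and CG10467 to -0.20 at 6 h. Its member peb rose to 0.23 at 1 h (n = 3), a value of 0.35 without culture 1 and 0.087 without culture 4 (adjusted p = 0.405), and its call was lost also without culture 2 (adjusted p = 0.057) or culture 3 (adjusted p = 0.0999). The gut marker Irk3 fell to -0.23 at 1 h and -0.38 at 6 h. Of the neuron list, Csp fell to -0.24 at 6 h and -0.35 at 24 h. There elav fell to -0.19 at 24 h, a call lost without culture 1, 2 or 3 (adjusted p = 0.055, 0.059 and 0.062), and unc-13 did not pass the test at any time.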
